A study of Pelvicachromis pulcher and blank sample with 173 samples.

How the data were processed

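DNA from *Pelvicachromis pulcher*, a West African cichlid, was treated with bisulfite, which turns unmethylated cytosine into a base read as T and leaves methylated cytosine read as C. Per the labels' protocols, 4 regions were then amplified by PCR, barcoded in another round of PCR, pooled and sequenced on an Illumina instrument. The series' notes place them upstream of the aromatase genes cyp19a1A and cyp19a1B, although the CpGs 7B, 56B and 68B bear positive positions. The series has 173 libraries, of which 171 held fish DNA and 2 were no-template controls, which carry what a PCR without added DNA yields. The labels gave each library a fish number, and 84 of the 87 fish contributed 2 libraries, either head and trunk or brain and gonad.

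The authors deposited read counts of each base at every CpG cytosine, at the other C and T positions and at the A and G positions of each amplicon, per the file headers, without normalization. They also deposited the percent methylation of each CpG, which the values show to be the reads with C over the reads with C or T. Recomputed from those columns, it differed from the deposited percent by at most 5e-11. A further deposited table held the count of reads with each string of bases over the CpGs of an amplicon, per the file headers, and 4 entries of it that name a reference and no library were not used. Bowtie, Bowtie2 and SAMtools are named in the submitters' processing notes. Their versions, settings and roles, and the reference sequence, are not given in the sources used here. CpG names such as -1291A were taken from the files, where A stands for cyp19a1A and B for cyp19a1B, and the number is a position in bases. The point from which positions are counted is not given in the sources used here, and no genome was used here, so the CpGs have no chromosome coordinates below.

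The 29 CpGs comprised 10 in the amplicon named AI (-1342A to -1220A) and 8 in AP (-274A to -65A) for cyp19a1A, and 7 in B2 (-72B to 68B) and 4 in BI (-1449B to -1296B) for cyp19a1B. The methylation of an amplicon in a library was the unweighted mean of the percent of its CpGs with at least 30 reads, given where at least 80% of them had that many. The median over libraries of the reads per CpG was 17628.5 for AI, 22176 for AP, 28314 for B2 and 16200.5 for BI. At those depths a counting interval of 95% (normal approximation, at 50% methylation) reached 0.738, 0.658, 0.582 and 0.770 percentage points to each side. The reads carry no molecular identifiers, so copies of the same molecule count more than once and intervals cover counting error only. Spread between fish was therefore the error used in every test. Reads were also limited at the low end, since 1 library of AI, 1 of AP, 1 of B2 and 12 of BI had a median under 500 reads per CpG, and 1 library of B2 and 1 of BI gave no amplicon value.

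Bisulfite conversion was computed from the share of reads with C at cytosines outside CpGs, leaving out 25 bases at each amplicon end. It lay between 98.4% and 99.6% with a median of 99.3%. The no-template controls had 105 to 215.5 reads per CpG, between 0.547% and 1.03% of the median depth, and methylation like that of fish DNA (46.4% and 58.9% at AI, 79.2% and 81.7% at AP, 70.5% and 75.0% at B2, 53.2% and 65.1% at BI). Fewer reads than the deeper control were found in 1 library of AI (fish 44), 1 of B2 (fish 14) and 5 of BI (fish 4, 14, 46, 47 and 49), whose values cannot be told from background by depth and are left out at a coverage minimum of 500 reads. No background was subtracted.

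Before the data were examined, the groups, tests and rule for named CpGs were fixed. The fish was the replicate. Differences between groups of fish were tested by permuting the group labels, differences between tissues of the same fish by flipping the sign of the within-fish difference, and differences among 3 or more groups by permuting labels on the sum of squares between groups. All tests were two-sided, except the last, which has no direction. All regroupings were enumerated up to 200000 of them, which makes a test exact, and 100000 were drawn otherwise. P-values were adjusted by the Benjamini-Hochberg method over the amplicons and tissues or ages of a comparison type, which held between 8 and 24 tests. Each CpG was tested in the same way and adjusted over the 29 CpGs of a comparison, with 0.05 as the threshold for both. Named CpGs are the ones with the highest and the lowest mean in each amplicon over all fish libraries, and in each comparison up to 5 past the threshold with the largest difference. All 4 amplicons were tested and are given in each comparison.

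The pairing of tissues came from the fish numbers in the labels. It was checked with positions where some fish carry A and G at the guanine of a CpG, a difference bisulfite does not touch. In 82 pairs of libraries the share of A at -1339A differed by at most 9.23 percentage points and at -1220A by at most 6.64 between both libraries of a fish, and 1 pair, from fish 14 at day 30, did not match. Only 20 fish carried A at -1339A and 24 at -1220A, against 66 and 63 that did not. Swaps among fish without A, or among carriers, would not show, so most pairings were not tested by this.

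The tests were tried on simulated data, in which the deviations of the real libraries from their group means were shuffled over all libraries compared. In 1 group 10 of 29 CpGs were shifted and reads were drawn at the real depths, with 10 runs per setting. The shuffling kept neither the pairing of tissues by fish nor unlike spreads of the groups, so the shares below hold only without them. For adult gonads, 18% of shifts by 10 points, 60% of shifts by 20 and 91% of shifts by 40 were found. The corresponding shares were 59%, 73% and 96% for females against Y males in 1-year gonads, 55%, 90% and 100% for pH in day 30 trunks, 42%, 73% and 98% for brain against gonad in adult males, and 42%, 66% and 94% for sets in neutral day 30 heads. With no shift, 0 of 10 runs gave a false call except for day 30 trunks, where 1 run of 10 did. With shifts of 20 points, 4, 2, 5, 4 and 5 of 10 runs in that order (adult gonads, 1-year gonads, day 30 trunks, brain against gonad, sets) had a false call, with 4, 3, 7, 4 and 7 false calls in all beside 60, 73, 90, 73 and 66 found.

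Alternatives changed 1 choice at a time. They were coverage minimums of 10, 100 and 500 reads, pooling reads over the CpGs of an amplicon, a logit scale, log2((percent + 1)/(101 - percent)), subtraction of unconverted reads, removal of libraries under 98% conversion, removal of CpGs that look like C/T variants, removal of 15 libraries whose description carries T0, tests without the fish block, within pH treatments, within sets, on set means, on sets RD6 3 and RD7 or T0 libraries only, females against Y males only, a quasi-binomial model of methylated and unmethylated reads with the dispersion from Pearson's chi-square, and leaving out each fish of groups of 2 to 5. Removal of CpGs whose own C or G varies between fish or that lie within 25 bases of an amplicon end, and removal of the unmatched library of fish 14, were added after seeing the data, as were the test of the sex difference across ages, with its alternatives, set means for pH at 1 year, and the comparison of base shares without fish 14. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used. No library was left out of the comparisons. The closest pair of libraries differed by 2.28 percentage points per CpG on average, with a chi-square of 8636 over the CpGs, so none was a copy of another.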

Results

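Methylation was measured at CpGs in 4 amplicons at the aromatase genes of *Pelvicachromis pulcher*, a cichlid whose sex depends on the environment and for which pH was the treatment here. Aromatase turns androgens into estrogens, with cyp19a1A coding for the form of the gonad and cyp19a1B for the form of the brain. Heads and trunks came from 7 fish at day 1, 27 at day 30 and 9 at day 60, each raised at neutral or acidic pH. Brains and gonads came from 27 fish sampled at 1 year, with 10 females (F), 7 males of the type coded Y and 10 fish coded J, and from 17 fish labelled only as adults, which have no pH label. The adults were 4 females and 5 Y, 4 R and 4 B males, with gonads from 4, 4 and 3 of these males. Y, R, B and J are the labels' own codes. Each fish also belonged to a set, and every set with a pH label had a single pH. Day 1 and day 60 fish came from sets RD7 (neutral) and RD6 3 (acidic) alone, and all adults came from a separate set. Summed over the 4 amplicons, the median reads per CpG of a library came to between 33091 and 208290, with a median of 84223.

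The amplicons differed in their level and in their spread between fish. Over the 171 libraries of fish DNA, the lowest AI mean was at -1220A (48.8% ± 17.8 SD) and the highest at -1337A (71.8% ± 15.5). At -1220A, 24 fish with A at its guanine averaged 29.4% and 63 others 56.5%. Among AI CpGs without such a variant, -1291A had the lowest mean (50.0% ± 19.3). AP ranged from 44.6% ± 1.17 at -274A to 96.4% ± 3.34 at -246A. Since -274A lies 17 bases from the amplicon start, primer bases may set its value, which was not tested. B2 means lay between 77.7% ± 22.4 at 7B and 86.8% ± 15.7 at 56B, and BI means between 50.3% ± 26.5 at -1412B and 81.1% ± 24.8 at -1296B. The bases around -1337A, with its CpG in the middle, read GCTGTCGCCGCGTAATCACGCA, and those around -246A read TACAAGCTCACGCCAACATGCA. Between fish of the same group and tissue the pooled SD was 3.20 percentage points at AI and 3.33 at AP, against 10.9 at B2 and 17.4 at BI.

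In adult gonads, females had less methylation than males in the amplicons of both aromatase genes, with the largest difference at the cyp19a1A amplicon AI. AI averaged 21.0% ± 5.87 (SD, n = 4) in gonads of adult females and 73.0% ± 7.64 (n = 11) in gonads of adult males, a difference of -52.1 percentage points. The 4 female values lay between 13.7% and 27.5%, and the lowest of the other gonads in the series had 57.9%. AP, the other cyp19a1A amplicon, averaged 66.7% ± 4.87 in females and 85.4% ± 4.45 in males. The AP value of the female fish 79, 68.9%, came from 271 reads per CpG, near the 215.5 of the deeper no-template control. With single fish left out the AP difference was -20.6 to -17.3. B2 averaged 64.0% ± 23.4 against 89.7% ± 8.39, and BI 58.7% ± 23.4 against 86.8% ± 8.63. For AI and AP the exact permutation p was 0.000733, the smallest that 1365 splits allow, and the adjusted p was 0.00293. Adjusted values were 0.0117 for B2 and 0.00586 for BI in the same exact test. Without the gonad of fish 79, in which 94.9% of B2 reads and 97.8% of BI reads had a single pattern, the B2 difference was -14.5 and the BI difference -17.0 (adjusted exact permutation p 0.0440 and 0.0293).

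By CpG, 21 of 29 were lower in gonads of adult females than of males and 0 higher, with all 10 of AI, 7 of the 8 in AP, 2 of 7 in B2 and 2 of 4 in BI. The permutation test gave 22 CpGs with an unadjusted p under 0.05, and the quasi-binomial model called 18. The differences were largest at -1291A (10.2% ± 6.00 in females and 68.5% ± 9.44 in males), -1437B (31.9% ± 36.2 and 89.4% ± 9.59), -1244A (12.9% ± 8.69 and 70.1% ± 9.58), -1285A (10.6% ± 7.24 and 67.7% ± 9.61) and -1322A (19.8% ± 6.74 and 73.0% ± 8.86). Each had an adjusted exact permutation p of 0.00152. Females against Y males alone gave -48.8 at AI, -16.9 at AP, -27.5 at B2 and -22.9 at BI and 0 CpGs past the threshold, with 4 fish on each side, where the smallest exact permutation p is 0.0286 and the adjusted values were 0.0571.

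In adult brains the sexes had similar means, with AI at 33.7% ± 3.51 in 4 females and 33.0% ± 2.82 in 13 males and BI at 46.2% ± 29.1 and 50.0% ± 24.2. The adjusted exact permutation p was 0.796 for each of the 4 amplicons. The permutation test called 0 CpGs in brain, with 0 at an unadjusted p under 0.05 and 0 by the quasi-binomial model. The sex difference in adult gonads differed from that in brains of the same fish by -52.6 points at AI and -19.6 at AP (adjusted exact permutation p 0.00293 for both), by -28.6 at B2 (0.00391) and by -18.3 at BI (0.507). It differed at 19 CpGs, 10 in AI, 7 in AP and 2 in B2, led by -1291A (-60.0), -1285A (-59.4), -1244A (-56.6), -1322A (-54.1) and -1329A (-53.0). Without fish 79 the value at B2 was -16.1 and its adjusted exact permutation p 0.0659.

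**Figure D1:**
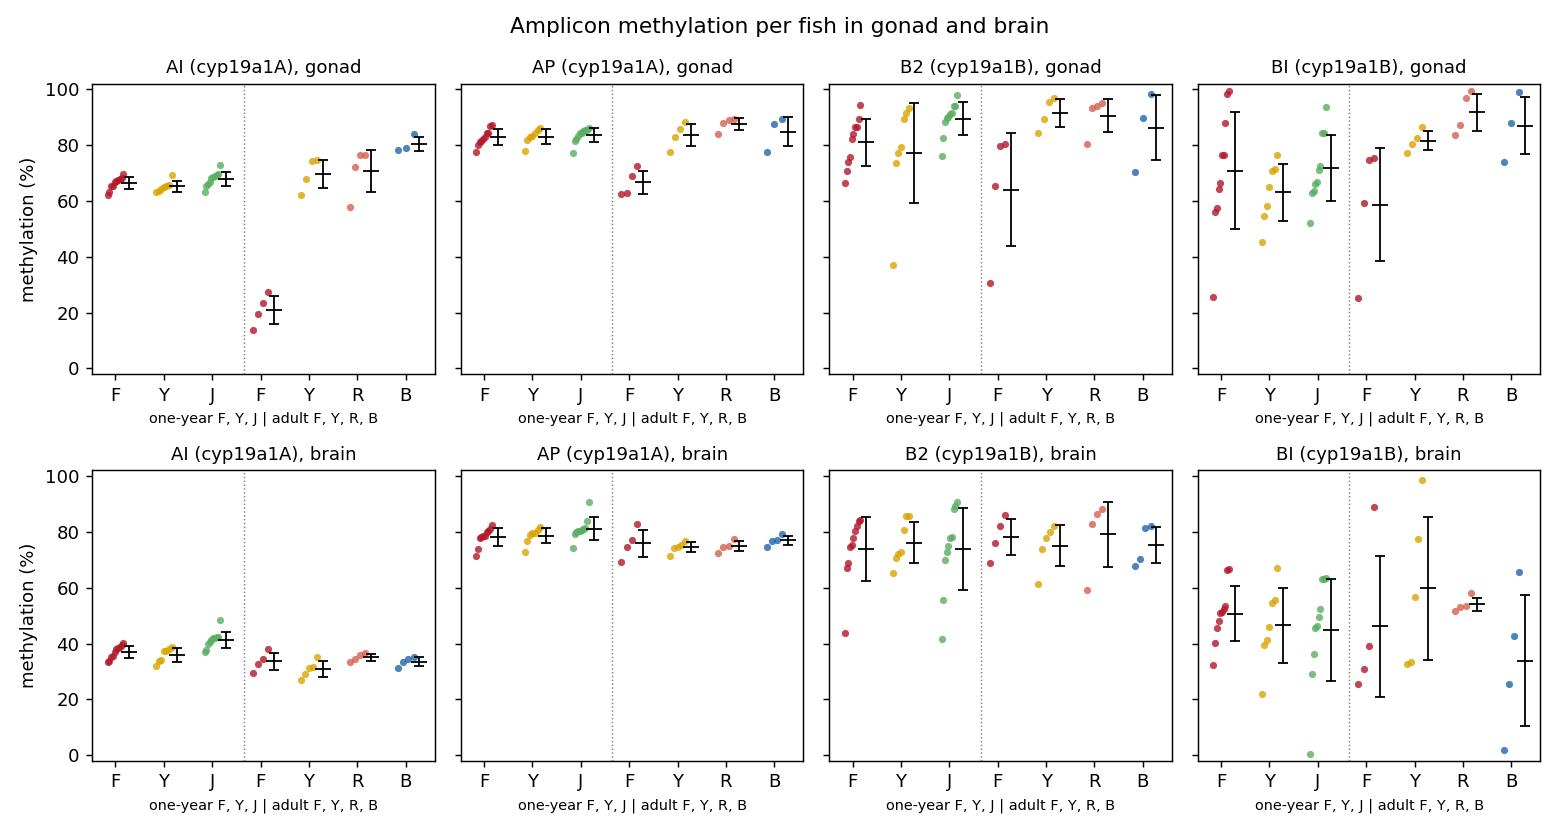
Methylation in percent of each amplicon (columns) in gonads (upper row) and brains (lower row), with a point per fish and the mean with its SD beside each group; F, Y, R, B and J are the labels' phenotype codes, with 1-year fish left and adults right of the dotted line. The 4 adult F gonads sit at 13.7% to 27.5% for AI, under every other gonad.

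**Figure D2:**
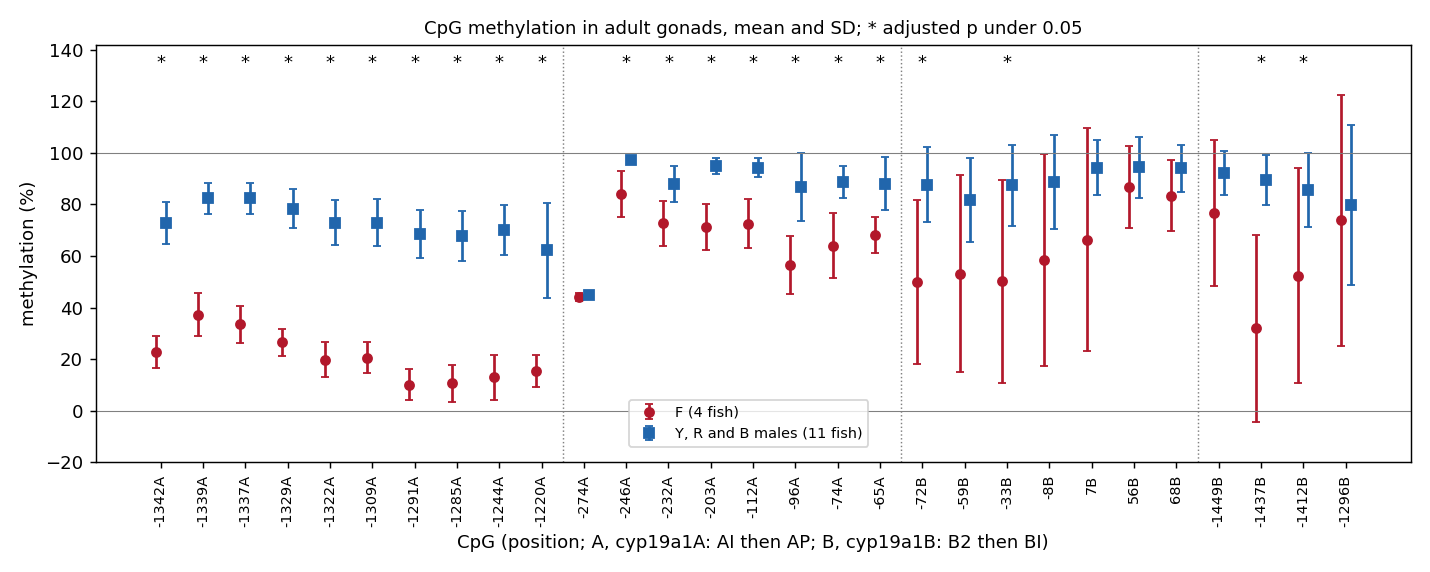
Methylation in percent (vertical axis) of the 29 CpGs (horizontal axis, by amplicon) in adult gonads, as means with SD bars for 4 F fish and 11 males; bars that pass 0% or 100% come from the symmetric SD, and an asterisk marks an adjusted permutation p under 0.05. All 10 CpGs of AI are lower in F fish, while -274A averages 44.0% in F fish and 45.0% in males.

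At 1 year no difference between females and Y males passed the threshold. AI averaged 66.3% ± 2.27 in gonads of 10 females and 65.2% ± 2.09 in gonads of 7 Y males, and 37.0% ± 2.36 and 35.9% ± 2.61 in their brains. AP gonad means were 82.8% ± 3.01 and 83.0% ± 2.79, B2 means 81.0% ± 8.90 and 77.3% ± 19.3 and BI means 70.8% ± 22.2 and 63.1% ± 11.0. The adjusted exact permutation p was 0.861 for each of the 8 tests in gonad and brain. The permutation test called 0 CpGs in each tissue, with 1 in each at an unadjusted p under 0.05 and 0 by the quasi-binomial model. Within sets the AI difference was 1.74 points in gonads and 2.63 in brains, and within pH treatments it was 1.11 and 1.72. Without variant and end CpGs it was -1.15 and -0.472.

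The sex difference in gonads itself differed between ages. In a test added after these values were seen, which permuted age within each sex, adults minus 1-year fish gave -53.1 points at AI (adjusted permutation p 0.00016), -18.4 at AP (0.000853), -29.4 at B2 (0.0217) and -35.8 at BI (0.0320). With Y males as the only adult males the values were -49.9, -16.7, -31.1 and -30.6 (adjusted permutation p 0.0008, 0.00372, 0.0320 and 0.0883). Without fish 79 the B2 and BI values were -18.2 and -24.7 (adjusted permutation p 0.101 and 0.191), without fish 77 that of BI -36.0 (0.0601), and on a logit scale the BI call ended as well (0.0727). In brains the same test gave -0.393 at AI (adjusted permutation p 0.866). Adults came from another set than 1-year fish, so age and set cannot be told apart here.

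Females at 1 year had more methylation of cyp19a1A in gonads than adult females. AI was 66.3% ± 2.27 at 1 year (n = 10) and 21.0% ± 5.87 in adults (n = 4), higher by 45.3 points, and AP was higher by 16.1, each with an adjusted exact permutation p of 0.00799. B2 and BI means were higher by 16.9 and 12.1 (adjusted exact permutation p 0.136 and 0.518), and by 5.75 and 1.02 without fish 79. In these gonads 18 CpGs were higher at 1 year, 10 in AI, 7 in AP and 1 in B2, with the largest differences at -1309A (71.7% ± 3.81 against 20.6% ± 6.16), -1285A (58.5% against 10.6%), -1342A (70.4% against 22.8%), -1322A (67.2% against 19.8%) and -1244A (59.9% against 12.9%).

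No difference between 1 year and adulthood passed the threshold in female brains or in either tissue of Y males. Gonad AI of Y males was 65.2% ± 2.09 at 1 year (n = 7) and 69.7% ± 5.85 in adults (n = 4, adjusted exact permutation p 0.188), and gonad BI was 63.1% ± 11.0 against 81.6% ± 3.97 (0.0556). Brain AI was 3.28 points higher at 1 year in females (adjusted exact permutation p 0.137) and 5.02 higher in Y males (0.0556). The permutation test called 0 CpGs in female brains, Y gonads and Y brains, with 1, 4 and 10 at an unadjusted p under 0.05, and the quasi-binomial model called 0 in each. Leaving out fish 73 brought the brain difference of females to 4.69 (adjusted exact permutation p 0.0448), and leaving out fish 83 that of Y males to 6.11 (0.0323).

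AI methylation was lower in brain than in gonad of the same fish in each group except adult females. Brain minus gonad was -29.3 ± 4.05 points in 1-year females (37.0% and 66.3%, lower in 10 of 10 fish), -29.4 ± 2.27 in Y males (35.9% and 65.2%, 7 of 7), -26.6 ± 4.05 in J fish (41.3% and 67.9%, 10 of 10) and -39.9 ± 8.72 in adult males (33.1% and 73.0%, 11 of 11). Adjusted exact sign-flip permutation p was 0.00781, 0.0284, 0.00781 and 0.00651. Adult females had the opposite order in 4 of 4 fish, 33.7% ± 3.51 in brain and 21.0% ± 5.87 in gonad, a difference of 12.7 ± 5.45, although 4 pairs cannot give an exact permutation p under 0.125. Without the pairing by fish its adjusted exact permutation p was 0.0440. AP differed by -4.62 ± 3.75 points in females (9 of 10 fish), -4.49 ± 1.66 in Y males (7 of 7) and -10.3 ± 4.20 in adult males (11 of 11; adjusted exact permutation p 0.0112, 0.0284 and 0.00651), and by -2.32 ± 4.15 in J fish (0.153). On a logit scale the AP calls of 1-year females and Y males ended (adjusted exact permutation p 0.556 and 0.290).

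At cyp19a1B, brains were less methylated than gonads in J fish and adult males. B2 differed by -15.7 ± 16.4 points in J fish (9 of 10 fish, adjusted exact permutation p 0.0217) and by -14.4 ± 10.3 in adult males (11 of 11, 0.00651), and BI by -26.8 ± 23.9 (8 of 10, 0.0195) and -30.8 ± 22.9 (10 of 11, 0.00977). Gonads of the J fish 46, 47 and 49 had 102.5 to 108 reads per CpG at BI, fewer than the 123 of the deeper no-template control. The J difference at BI lost its call at a coverage minimum of 500 reads (-28.4, adjusted exact permutation p 0.0521). BI differences of -20.1 ± 26.5 points in 1-year females and -16.5 ± 12.0 in Y males gave adjusted exact permutation p of 0.0661 and 0.0521, and 0.0314 and 0.0466 without the pairing by fish.

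CpGs lower in brain numbered 16 in 1-year females, 15 in Y males, 18 in J fish and 19 in adult males, with all 10 of AI in each. A single CpG was higher in brain in each group, -203A at 1 year and -232A in adult males, both of AP. The 5 largest differences in females were in AI, led by -1322A (28.3% ± 3.50 in brain and 67.2% ± 2.82 in gonad) and -1285A (22.8% and 58.5%), followed by -1291A, -1309A and -1244A. In Y males -1322A (29.0% and 67.2%), -1285A, -1291A, -1244A and -1309A led. In J fish -1322A (34.6% and 71.6%), -1285A and -1291A were followed by -1437B (36.5% and 67.8%) and -1449B (38.2% and 69.0%). In adult males -1285A (17.2% ± 2.63 and 67.7% ± 9.61), -1291A, -1322A and -1244A were followed by 7B (49.7% ± 23.5 and 94.2% ± 10.8). For adult females the permutation test called 0 CpGs, with 0 at an unadjusted p under 0.05 and 0 by the quasi-binomial model.

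Heads of young fish had less AI methylation than trunks and more AP methylation. At AI heads and trunks had 68.8% ± 1.22 and 77.9% ± 3.06 at day 1 (lower in heads in 7 of 7 fish), 64.5% ± 3.11 and 73.0% ± 2.89 at day 30 (25 of 26) and 60.9% ± 2.77 and 70.4% ± 3.79 at day 60 (9 of 9). AP was higher in heads by 5.03 ± 2.32 points at day 1 (7 of 7), 2.91 ± 4.53 at day 30 (19 of 26) and 4.27 ± 2.43 at day 60 (9 of 9). The adjusted p from sign-flip permutation was 0.0268, 0.00012 and 0.00938 for AI and 0.0268, 0.00938 and 0.00938 for AP. B2 differed by -8.66 ± 13.5 points at day 30 (lower in heads in 19 of 25 fish, adjusted permutation p 0.00938) and by -8.11 ± 13.9 at day 60 (0.164), and BI passed the threshold at no age. AI had 7 CpGs lower in heads at day 1 and 10 at day 30 and day 60, and AP had 3, 2 and 2 higher. Among CpGs past the threshold, the largest differences at day 1 were at -1322A (66.9% ± 4.66 in heads and 80.2% ± 1.83 in trunks), -1244A, -1291A, -1285A and -1342A. At day 30 they were at -1291A (55.3% ± 4.68 and 66.7% ± 3.58), -1322A, -1285A, -1220A and -1309A, and at day 60 at -1291A (49.2% ± 4.32 and 61.6% ± 4.85), -1309A, -1322A, -1285A and -1244A.

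Fish coded J had slightly more AI methylation in the brain than both other 1-year groups. Their mean was 41.3% ± 3.12 (n = 10), against 37.0% ± 2.36 in females and 35.9% ± 2.61 in Y males, differences of 4.28 and 5.40 points with an adjusted exact permutation p of 0.0145 for each. Against females, 8 CpGs of AI and 2 of AP were higher in J brains, led by -74A (77.5% and 69.7%), -1309A (46.5% and 38.8%), -1329A (50.3% and 42.7%), -65A (76.6% and 69.7%) and -1244A (34.3% and 27.8%). Against Y males 1 CpG passed the threshold, -1337A (57.7% and 50.1%, adjusted exact permutation p 0.0418). In gonads J means were 1.57 points over females and 2.65 over Y males at AI (adjusted exact permutation p 0.336 and 0.143) and 8.55 and 12.2 over them at B2 (0.129 and 0.143). There the permutation test called 0 CpGs in both comparisons, with 9 and 3 at an unadjusted p under 0.05 and 3 and 0 by the quasi-binomial model. Of the 10 J fish 8 were from sets RD1 and RD4, which held 2 of the females and 1 Y male. Within sets the brain difference was 4.83 points against females and 7.35 against Y males (adjusted exact permutation p 0.311 and 0.2), and within pH treatments 4.76 and 6.48 (0.0284 and 0.0423). These values weigh each set or treatment equally. In set RD6 3 the only J fish had 48.3% and the only female 33.8%. J and female means were 41.0% and 38.4% in RD1, 40.8% and 40.1% in RD4 and 36.8% and 35.3% in C70. Neutral J and female brains averaged 40.9% ± 1.58 and 39.0% ± 0.814, and acidic ones 42.5% ± 8.11 (n = 2) and 35.0% ± 1.42. Within sets J against Y allows 40 regroupings, whose smallest exact permutation p of 0.025 is the unadjusted value at AI and AP, and it passes only if 9 of the 16 tests have a p that low. J against F allows 240, with a smallest of 0.00417 and 0.0583 at AI. Within sets 0 CpGs passed in either comparison, and within pH treatments 8 against females and 0 against Y males. Without CpGs that carry sequence variants or lie near an amplicon end, the brain difference from females was 6.46 (0.0100) and that in gonads 4.34 (0.0346), both by exact permutation.

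The pH at which young fish were raised gave no amplicon difference past the adjusted threshold. At day 30, with 6 sets, AI averaged 63.8% ± 2.65 in neutral and 65.1% ± 3.51 in acidic heads (13 fish each), and 73.4% ± 2.04 and 72.5% ± 3.47 in trunks (13 and 14 fish), with an adjusted permutation p of 0.655 for both. Over set means the neutral minus acidic difference was -1.14 in heads and 1.04 in trunks, and between sets RD7 and RD6 3 alone it was -2.10 and 3.02. The largest young difference was at B2 in day 60 heads, 61.8% ± 9.27 in 4 neutral and 88.6% ± 6.78 in 5 acidic fish (exact permutation p 0.00794, adjusted 0.190). Trunk AI at day 1 was 79.9% ± 1.78 in 4 neutral and 75.3% ± 2.36 in 3 acidic fish (exact permutation p 0.0286, adjusted 0.343), and without variant and end CpGs the difference of 4.55 points became -0.761. Of the 24 tests 3 had an unadjusted p under 0.05. The permutation test called 0 CpGs in each of the 6 comparisons. At an unadjusted p under 0.05 there were 6, 1 and 6 in heads of days 1, 30 and 60 and 0, 1 and 3 in trunks, and the quasi-binomial model called 1 in day 60 heads and 0 in the others. Without T0 libraries, and so without set RD7 and most of RD6 3, 5 CpGs were called in day 30 trunks. That test permuted fish although each set had a single pH, so these calls cannot be told from differences between sets. Whether the pH difference differed between trunk and head was tested as well, with a lowest adjusted permutation p of 0.159 over 12 amplicon tests and 0 CpGs called by the permutation test, against 4, 2 and 5 at an unadjusted p under 0.05. Each pH had 1 set at day 1 and at day 60, so pH and set cannot be told apart there.

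At 1 year, pH was likewise without an amplicon difference past the adjusted threshold in females, Y males or J fish. Neutral females had a mean brain AI of 39.0% ± 0.814 and acidic females of 35.0% ± 1.42 (n = 5 each, exact permutation p 0.00794, adjusted 0.190), and their gonad BI means were 85.6% ± 14.2 and 56.0% ± 18.9 (exact permutation p 0.0238, adjusted 0.190). In female brains 5 CpGs of AI were higher at neutral pH, -1337A (55.2% ± 2.43 and 48.4% ± 1.64), -1244A (31.1% and 24.4%), -1322A (31.1% and 25.4%), -1329A (45.3% and 40.2%) and -1291A (24.9% and 20.9%), each with an adjusted exact permutation p of 0.0460. The neutral brain of fish 44 had 83 reads per CpG at AI, fewer than either no-template control, and at coverage minimums of 100 and 500 reads 0 CpGs were called. With any of the 10 fish left out (44, 54, 55, 61, 62, 63, 65, 67, 68 or 69) the count was also 0, although the smallest exact permutation p, 0.00794, is the same for 4 against 5 fish. Elsewhere the permutation test called 0 CpGs, with 5 at an unadjusted p under 0.05 in female gonads, 1 in Y gonads, 0 in Y brains, 1 in J gonads and 0 in J brains, and 0 by the quasi-binomial model in each. Only 2 Y males were neutral and only 2 J fish acidic. Of the 5 acidic females 4 were from set C70, and no set held both pH treatments. Brain AI of females averaged 38.4%, 40.1% and 38.8% in the neutral sets RD1, RD4 and RD7 (1, 1 and 3 fish) and 35.3% and 33.8% in the acidic sets C70 and RD6 3 (4 and 1). Over set means, an alternative added later, the difference was 4.54 points with an exact permutation p of 0.1, the smallest that 3 sets against 2 allow, so differences between sets cannot be excluded.

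The 3 male types did not differ past the adjusted threshold in either tissue. Gonad AI averaged 69.7% ± 5.85 in 4 Y, 70.7% ± 8.74 in 4 R and 80.5% ± 3.14 in 3 B males (adjusted exact permutation p 0.465). Brain AI averaged 30.8% ± 3.12 in 5 Y, 35.1% ± 1.47 in 4 R and 33.5% ± 1.70 in 4 B males (exact permutation p 0.0561, adjusted 0.449). Over the 3 types the permutation test called 0 CpGs, with 1 in gonads and 2 in brains at an unadjusted p under 0.05 and 0 by the quasi-binomial model. Between pairs of types the lowest of 24 adjusted exact permutation p was 0.411. Each pair also gave 0 CpGs by permutation and by the quasi-binomial model, with an unadjusted p under 0.05 at 4 CpGs for Y against R and 2 for R against B in brains and at 0 in the others.

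From day 1 to day 60, AI methylation differed between ages in heads of both sets sampled throughout and in trunks of the neutral set, with its highest mean at day 1. In acidic heads (set RD6 3) it was 69.7% ± 1.06 at day 1, 63.4% ± 1.70 at day 30 and 61.3% ± 3.33 at day 60 (3, 4 and 5 fish, adjusted exact permutation p 0.0118). In neutral heads (set RD7) it was 68.1% ± 0.855, 61.3% ± 2.75 and 60.4% ± 2.26, and in neutral trunks 79.9% ± 1.78, 72.9% ± 3.00 and 69.3% ± 2.10 (4 fish each, adjusted exact permutation p 0.0133 and 0.00554). Acidic trunks had 75.3% ± 2.36, 69.9% ± 1.81 and 71.4% ± 4.80 (adjusted exact permutation p 0.320, or 0.0438 without fish 20). Neutral heads also differed between ages at AP (87.7% ± 0.795, 83.1% ± 3.35 and 86.5% ± 0.330, adjusted exact permutation p 0.00277) and at B2 (85.2% ± 6.75, 88.6% ± 7.52 and 61.8% ± 9.27, 0.0118). Between the highest and the lowest AP mean lay 4.66 points, and 3.09 without fish 29, while the B2 call ended on a logit scale (adjusted exact permutation p 0.0964). The T0 libraries hold all day 30 fish of set RD7 and most of set RD6 3, so in RD7 day 30 and T0 cannot be told apart. This bears on AP in neutral heads, where day 30 had the lowest mean. Without T0 libraries the neutral set has only days 1 and 60, with 4 fish each. No exact permutation p under 0.0286 is possible there, and 10 of the 16 tests would need a p that low to pass, so its calls could hardly remain. The adjusted exact permutation p was then 0.0914 for each of the 5 results past the threshold. The AI ranges were then 8.79 points in acidic heads, 7.66 in neutral heads and 10.6 in neutral trunks, against 8.43, 7.66 and 10.6 with all fish, the B2 range 23.4 against 26.8 and the AP range 1.22 against 4.66. At AI in the neutral set day 30 lay between the other days, so those ranges could not change.

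Age differences passed the threshold at 9 CpGs in acidic heads, 14 in neutral heads and 10 in neutral trunks. In acidic heads the widest of these were at -1285A (67.4% ± 3.64, 57.9% ± 3.26 and 52.4% ± 3.66 at days 1, 30 and 60), -1291A, -1342A, -1329A and -1322A. In neutral trunks they were at -1291A (72.0% ± 2.16, 63.8% ± 3.13 and 59.0% ± 3.49), -1244A, -1342A, -1322A and -1285A. In neutral heads they were at -33B (94.5% ± 8.27, 80.4% ± 21.7 and 42.1% ± 13.8), 68B (93.9%, 86.7% and 51.0%), -8B, 7B and -1291A (59.2%, 49.3% and 47.3%). In acidic trunks the permutation test called 0 CpGs, with 5 at an unadjusted p under 0.05 and 0 by the quasi-binomial model, and 1 without fish 17. The count in acidic heads was 2 without fish 10 and 5 without fish 20, 21 or 22, and that in neutral heads was 8 without fish 23. Without the T0 libraries 0 CpGs were called in heads and trunks of the neutral set, where the smallest exact permutation p is 0.0286 and 17 CpGs at that value would be needed, with 14 in heads and 9 in trunks. Where the day 30 mean lay between the others the range could not change, and elsewhere -274A, part of each count, fell to 0.533, 0.359 and 0.338 points in acidic heads, neutral heads and neutral trunks, from 2.34, 2.48 and 2.88. In neutral heads -96A fell to 6.05 from 10.3 and -1220A to 6.11 from 8.17.

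**Figure D3:**
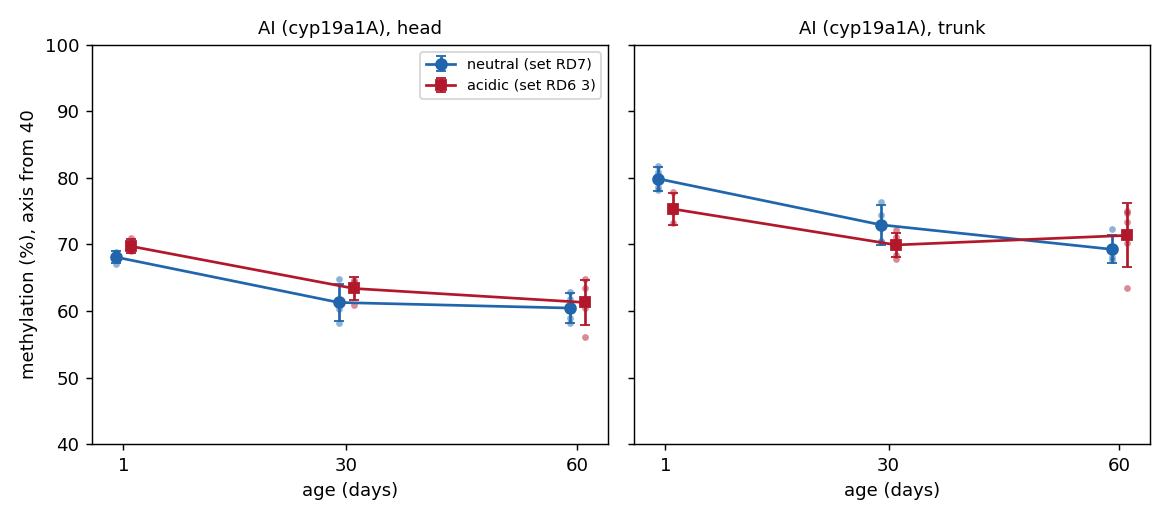
AI methylation in percent (vertical axis, starting at 40) against age in days in heads and trunks of the neutral set RD7 and the acidic set RD6 3, with a faint point per fish and the mean with SD; points of each set are moved 1 day to the side to keep them apart. Means in heads go from 68.1% and 69.7% at day 1 to 60.4% and 61.3% at day 60.

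Sets raised at the same pH differed past the threshold at some CpGs at day 30, and -1339A had the widest range among those. Wider ranges that did not pass included 39.8 points at -1449B in neutral heads and 61.7 at -1296B in acidic trunks. In neutral heads -1339A averaged 40.9% ± 1.27 in set RD1 (n = 5), 80.5% ± 2.51 in RD4 (n = 4) and 74.7% ± 1.56 in RD7 (n = 4), and -1220A averaged 60.7% ± 2.49, 31.6% ± 2.89 and 53.9% ± 2.72. Next among those in neutral heads came -1244A (60.0%, 67.7% and 54.2%), -1285A and -1291A, and in neutral trunks -1339A (42.4%, 84.6% and 82.0%) and -1220A (70.1%, 37.7% and 68.7%) were followed by -1244A, -1291A and -1337A. In acidic trunks -1339A averaged 45.8% ± 9.69 in set RD6 3, 80.3% ± 1.44 in RD10 and 85.4% ± 2.33 in C70. Both -1339A and -1220A have an A/G polymorphism at their guanine. CpGs past the threshold numbered 10 in neutral heads, 6 in neutral trunks and 1 in acidic trunks. Both neutral counts include -1339A, -1220A and -274A, which lies near an amplicon end and had ranges of 2.58 and 2.56 points. The CpG of acidic trunks is -1339A. In acidic heads the permutation test called 0, with 4 at an unadjusted p under 0.05 and 1 by the quasi-binomial model. Without T0 libraries, and so without set RD7, the counts were 0 in neutral heads and trunks, where 5 fish against 4 give no exact permutation p under 0.00794 and 5 CpGs at that value would be needed. Each had 4 at it, and the CpGs called with all fish kept a median of 33.3% of their range in heads and 37.3% in trunks, as -1244A with 7.78 and 3.87 points, from 13.5 and 9.63. At -1339A and -1220A RD7 lay between the other sets, so their ranges could not change. In acidic trunks set RD6 3 was then left with a single fish, and the ranges were 41.6 points at -1339A, from 39.6, and 36.5 at -59B, from 10.6. Neutral trunks gave 11 CpGs without fish 6, acidic heads 1 without fish 14 or 35, and acidic trunks 2 without fish 13 or 36 and 0 without fish 39 or 40.

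Over whole amplicons, set means ranged over 5.14 points at AI in neutral heads, 6.04 at AI in acidic trunks and 19.1 at B2 in acidic heads, each with an adjusted permutation p of 0.0390. All 3 calls ended on a logit scale and without the trunk library of fish 14, where the lowest adjusted permutation p was 0.0584. The AI call in neutral heads also ended without any of fish 1, 3, 4, 5, 6, 7, 8, 27, 28 or 29 (4.14 to 5.31 points) and without T0 libraries (2.59), and without variant and end CpGs the range was 8.49. In acidic trunks the AI call ended without fish 14, 16, 17, 39, 40 or 42 (5.10 to 6.12), and the B2 call in acidic heads without fish 14, 17, 35, 36, 37, 39, 40, 42 or 43 (15.9 to 20.0). At AP neutral trunks had a range of 8.21 points (adjusted permutation p 0.124), and 9.87 without fish 2 (0.0292).

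Other amplicon differences did not pass the threshold, with a lowest adjusted permutation p of 0.0808. Brain minus gonad was -7.20 at B2 in 1-year females, -1.21 at B2 in Y males and 9.24 at AP, 14.2 at B2 and -12.5 at BI in adult females. Head minus trunk was 1.74 at B2 and -7.71 at BI at day 1, and at BI -4.43 at day 30 and -7.52 at day 60. Females minus males in brains gave -0.384 at AP, -2.33 at B2 and 4.10 at BI at 1 year and 0.581 at AP and 1.91 at B2 in adults, and the gonad minus brain sex difference at 1 year was -0.0333 at AI, 0.130 at AP, 5.99 at B2 and 3.62 at BI. J minus F gave 0.679 at AP and 0.838 at BI in gonads and 2.98 at AP, 0.0767 at B2 and -5.81 at BI in brains, and J minus Y 0.425 at AP and 8.56 at BI and 2.60 at AP, -2.25 at B2 and -1.72 at BI. For 1 year minus adult, female brains had 2.26 at AP, -4.49 at B2 and 4.51 at BI, Y gonads -0.531 at AP and -14.2 at B2 and Y brains 4.13 at AP, 1.09 at B2 and -13.1 at BI.

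Neutral minus acidic pH gave -1.62 at AI, -0.381 at AP, -0.736 at B2 and -5.13 at BI in day 1 heads, 2.94 at AP, -6.65 at B2 and -6.01 at BI in day 1 trunks, 1.30 at AP, 3.27 at B2 and 9.76 at BI in day 30 heads and 2.67 at AP and 13.7 at BI in day 30 trunks, where B2 averaged 87.6% and 89.6%. Day 60 heads had -0.842 at AI, 0.378 at AP and 3.56 at BI and day 60 trunks -2.09 at AI, 1.25 at AP, -6.90 at B2 and -8.11 at BI. At 1 year it was -1.95 at AI, 2.12 at AP and 4.21 at B2 in female gonads, 4.35 at AP, 3.75 at B2 and -5.01 at BI in female brains, -0.162 at AI, 2.27 at AP, 11.1 at B2 and 14.6 at BI in Y gonads and -2.83 at AI, 0.895 at AP, 3.84 at B2 and 20.0 at BI in Y brains. J fish had 0.622 at AI, 4.72 at AP, -4.62 at B2 and 6.05 at BI in gonads and -1.60 at AI, -1.64 at AP, -6.42 at B2 and -11.8 at BI in brains. Between trunk and head the pH difference differed by 6.17 at AI, 3.32 at AP, -5.91 at B2 and -0.879 at BI on day 1, 2.12 at AI, 1.37 at AP, -6.26 at B2 and 5.79 at BI on day 30 and -1.25 at AI, 0.873 at AP, 19.9 at B2 and -11.7 at BI on day 60.

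Ranges over the 3 male types were 4.00 at AP, 5.27 at B2 and 10.2 at BI in gonads and 2.57 at AP, 4.04 at B2 and 25.8 at BI in brains. In gonads Y minus R was -0.990 at AI, -4.00 at AP, 0.907 at B2 and -10.2 at BI, Y minus B -10.8 at AI, -1.24 at AP, 5.27 at B2 and -5.37 at BI and R minus B -9.77 at AI, 2.76 at AP, 4.36 at B2 and 4.79 at BI. In brains these were -4.21 at AI, -0.381 at AP, -4.04 at B2 and 5.69 at BI, then -2.70 at AI, -2.57 at AP, -0.311 at B2 and 25.8 at BI, and 1.51 at AI, -2.19 at AP, 3.73 at B2 and 20.1 at BI. Ranges over ages were 1.98 at AP, 11.3 at B2 and 8.42 at BI in acidic heads, 5.39 at AI, 0.292 at AP, 1.65 at B2 and 5.85 at BI in acidic trunks, 7.46 at BI in neutral heads and 1.99 at AP, 10.8 at B2 and 12.8 at BI in neutral trunks. Ranges over sets at day 30 were 5.27 at AP, 15.6 at B2 and 15.6 at BI in neutral heads, 1.16 at AI, 7.92 at B2 and 24.6 at BI in neutral trunks, 3.40 at AI, 4.30 at AP and 23.9 at BI in acidic heads and 1.83 at AP, 6.14 at B2 and 27.0 at BI in acidic trunks.

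Reads with no methylated CpG at AI made up 47.2% ± 7.48 of the reads in gonads of adult females (n = 4) and 6.66% ± 3.56 in gonads of adult males (n = 11), and reads with all 10 CpGs methylated 1.14% ± 0.732 and 37.4% ± 14.3. Both differences had an adjusted exact permutation p of 0.0129 over 132 tests of read patterns. Fully methylated reads were also fewer in these females at AP (31.2% ± 5.83 and 65.6% ± 16.7, 0.0181) and B2 (28.8% ± 22.3 and 63.2% ± 15.9, 0.0322), by exact permutation. In brains of 1-year females, AI reads without methylation made up 22.4% ± 2.60, against 9.79% ± 2.45 in their gonads, and in adult males 21.2% ± 5.08 of brain reads against 6.66% of gonad reads (adjusted exact permutation p 0.0172 for both). Fully methylated AI reads in adult males were 2.77% ± 0.952 in brain and 37.4% in gonad (adjusted exact permutation p 0.0129). None of the read patterns differed past the adjusted threshold between females and Y males at 1 year or between pH treatments at day 30.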

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

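All tests of explanations here were chosen after the results were seen, except the test of read depth on the spread of cyp19a1B, and the test of the sex difference across ages was added after the data were seen as well. A single fish lay far from the rest of its group in 3 of the 84 combinations of group and amplicon tested, where chance alone would give about 4.2 (1 in 20). Brain AI of fish 66, an acidic 1-year Y male, was 32.0%, against 37.9% ± 0.683 in the other 4, and it was the only fish of its group from set C70. Gonad B2 of fish 81, an adult R male, was 80.3%, with 93.2% the lowest of the other 3. Head BI of fish 23, neutral at day 1, was 24.6%, against 73.1% ± 4.35 in the other 3.

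The sex difference differed between tissues and between ages. Between gonads and brains of adults it differed by -52.6 points at AI, -19.6 at AP and -28.6 at B2, and between adult and 1-year gonads by -53.1 at AI, -18.4 at AP, -29.4 at B2 and -35.8 at BI. Without the adult female fish 79 the B2 value was -16.1 between tissues and -18.2 between ages, and the BI value between ages -24.7, none of them past the threshold (adjusted permutation p 0.0659, 0.101 and 0.191). Without fish 77 the BI value between ages was -36.0 (adjusted permutation p 0.0601).

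Low cyp19a1A methylation in gonads of adult females was weighed against 3 technical explanations. Without CpGs that vary in sequence the AI difference was -53.6 (adjusted exact permutation p 0.00293), which argues against such variants as its cause. No AI CpG lies within 25 bases of an amplicon end, so this removal did not test primer bases. The shallowest of these gonads had 8172.5 reads per CpG at AI, 45.2 times the deeper no-template control. At AP the gonad of fish 79 had only 271, near the 215.5 of the deeper control, so depth was no argument there. A shift shared by all adult libraries would lower gonad AI of adult Y males too, by about the 45.3 points that separate adult from 1-year females, and theirs was 4.51 points above that of 1-year Y males (69.7% ± 5.85 and 65.2% ± 2.09). The difference between adult females and males, -52.1 points at AI, passed the threshold in a comparison fixed beforehand, and what causes it stays open. Against 1-year fish, age and set cannot be told apart, since all adults came from a single set.

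The spread between fish of the same group, with an SD of 17.4 points at BI and 10.9 at B2 against 3.20 at AI, was weighed against the depth and the number of template molecules. With CpGs under 500 reads left out, 92.6% of the variance of BI remained, which argues against low read depth. In fish that carry both bases at a variable position of BI, the share of A in the fish's other library had an SD of 26.0 points (40 fish). At 2 positions of AI it was 11.7 and 4.75 (19 and 24 fish). Fish 14 was in both AI counts, and the permutation treated its values as separate. The variance was 9.25 times as large (permutation p 1e-05, the smallest that the draws can give), and without fish 14, whose libraries do not match, the SDs at AI were 2.59 and 2.27 and the ratio 112 (same p), so few template molecules per PCR may widen the values of cyp19a1B. Differences between fish in cyp19a1B methylation itself stay open as well, since no test here separates them from the sampling of molecules, and for B2 no variable position was tested.

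Positions outside the main measurement showed sequence differences between fish. Over 20% of reads had A at the guanine of -1339A in 39 libraries and at that of -1220A in 48, and A or G at the cytosine of -112A in 14. For the differences between sets at day 30, -1339A averaged 40.1% in 20 carriers and 71.2% in 66 other fish, a difference of -40.6 points relative to the other AI CpGs of the same libraries (permutation p 1e-05, the smallest that the draws can give). At -1220A it was -30.6, with 29.4% in 24 carriers and 56.5% in 63 others. Carriers came from 2 of 7 sets for -1339A and 3 of 7 for -1220A, so a sequence difference that removes the CpG may account for the set differences at both. It leaves those at -1244A, -1285A and -1291A open, and without variant and end CpGs the AI range among neutral heads was 8.49 points. All day 30 libraries of set RD7 carry T0, so that set and T0 cannot be told apart. Without T0 libraries the ranges at these CpGs in neutral heads were 7.78, 4.28 and 1.66 points, from 13.5, 10.8 and 9.43.

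Fish 14 stood apart at both positions. Its head had 0.602% A at -1339A and 53.1% at -1220A, and its trunk 25.0% and 29.2%, where other carriers had 43.8% to 54.6% and 46.1% to 54.4%. At B2 its trunk had 19 reads per CpG.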

How the results depend on the processing

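Removal of variant and end CpGs and of the trunk library of fish 14 were added after seeing the data, as were all alternatives of the sex difference across ages and set means for pH at 1 year, and the other alternatives were planned. Over 19 settings, 2231 of 2300 amplicon differences kept their direction and side of the threshold and 593 of 612 CpG counts stayed within 1.5 times, and with single fish left out 1104 of 1188 and 270 of 293 did. Many of these values could not move. Removal of T0 libraries or of the trunk library of fish 14, all from day 30, left the differences of every comparison without them as they were. The shares therefore overstate how far the results were tried. Sign changes numbered 36 over the settings and 51 with single fish left out, and 0 of them were of a difference past the threshold. No call changed in 7 settings: a coverage minimum of 10, pooled reads, the conversion correction, removal of C/T variant CpGs, set means at day 30 (which cannot pass the threshold), sets RD6 3 and RD7 only and T0 libraries only. Removal of libraries under 98% conversion left out none and gave no values. Where nothing else is said, the cause of a change was not tested.

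At coverage minimums of 100 and 500 reads the permutation test called 0 and 0 CpGs for pH in female brains, and at 500 the J brain minus gonad value at BI was -28.4. On the logit scale, brain minus gonad at AP was -0.14 in females and -0.12 in Y males, the B2 age range in neutral heads 2.54, and the set ranges 0.34 for AI in neutral heads, 1.73 for B2 in acidic heads and 0.39 for AI in acidic trunks, all no longer past the threshold. Values that newly passed it there were -1.52 at BI for brain minus gonad in Y males and -0.82 at BI for head minus trunk at day 1, and the sex difference across ages at BI (-3.55) no longer did.

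Without T0 libraries, which leaves fewer day 30 fish, the age ranges 8.79 (AI, acidic heads), 7.66 (AI), 1.22 (AP) and 23.4 (B2) in neutral heads and 10.6 (AI, neutral trunks) and the set ranges 2.59 (AI, neutral heads) and 5.69 (AI, acidic trunks) no longer passed. The permutation test then called 5 CpGs for pH in day 30 trunks, where fish were permuted although each set had a single pH. It called 0 for age in neutral heads and 0 in neutral trunks, and 0 and 0 for sets in neutral heads and neutral trunks. For sets in acidic trunks RD6 3 was left with a single fish, and -59B had a range of 36.5 points, from 10.6. In the 4 neutral comparisons the fish left give no exact permutation p under 0.0286 (age) and 0.00794 (sets). To pass, 17 and 5 CpGs, or 10 and 3 of 16 amplicon tests, would have to reach it. The CpGs called between sets with all fish also kept only a median of 33.3% (heads) and 37.3% (trunks) of their range. Without the trunk library of fish 14 the set ranges were 5.14 (AI, neutral heads), 19.1 (B2, acidic heads) and 5.50 (AI, acidic trunks), where the heads are the same fish and only the adjustment over all set tests moved. Without variant and end CpGs, J minus F in gonads at AI was 4.34, now past the threshold, and the set ranges 19.1 (B2, acidic heads) and 4.84 (AI, acidic trunks) were not, with 2 CpGs in neutral trunks and 0 in acidic trunks and fewer CpGs tested.

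Without the pairing of tissues by fish (no replicate block), BI in females (-20.1) and Y males (-16.5) and AI in adult females (12.7) newly passed for brain minus gonad, and none of the other 37 values changed its call. Within pH treatments J against Y brains gave 0 CpGs. Within sets the J minus F and J minus Y brain values at AI were 4.83 and 7.35, with 0 and 0 CpGs, where J against Y allows no exact permutation p under 0.025. Females against Y males alone gave -48.8, -16.9, -27.5 and -22.9 in adult gonads and 0 CpGs, where 4 fish against 4 give no exact permutation p under 0.0286, and -30.6 at BI across ages. The quasi-binomial model called 3 CpGs for J against F gonads, 1 for pH in day 60 heads, and 1 and 3 for sets in acidic heads and trunks.

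With single fish left out, the CpGs for pH in female brains numbered 0 to 0, those for age 2 to 9 in acidic heads, 8 to 16 in neutral heads and 0 to 1 in acidic trunks, and those for sets 0 to 1 in acidic heads, 0 to 2 in acidic trunks and 5 to 11 in neutral trunks. The AI age range in acidic trunks was 4.11 to 6.43. Brain AI at 1 year was 1.89 to 4.69 above adults in females and 4.02 to 6.11 in Y males. Set ranges were 15.9 to 21.8 (B2, acidic heads), 5.10 to 6.70 (AI, acidic trunks), 4.14 to 6.31 (AI, neutral heads) and 7.24 to 9.87 (AP, neutral trunks), and the B2 sex difference in adult gonads against brains was -34.6 to -16.1. Between ages the gonad sex difference was -34.8 to -18.2 at B2 and -41.3 to -24.7 at BI. The fish behind each change are named beside the results.

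Among uncalled differences whose sign changed, pooled reads gave 0.0661 at AP for Y minus R brains, and without C/T variant CpGs R minus B gonads had -6.01 at BI. The logit scale gave 0.0605 at AP for J brain minus gonad, 0.0517 (gonads) and 0.0323 (brains) at AP and 0.0827 (brains) at B2 for 1-year F minus Y, -0.17 at BI for J minus F gonads, -0.00489 and 0.0778 at B2 for J minus F and J minus Y brains, 0.49 at B2 for pH in day 1 heads, -0.14 at B2 for pH in 1-year female gonads, -0.21 at BI for R minus B gonads, -0.0146 at B2 for 1-year minus adult Y brains, and 0.00798 and -0.00973 for the pH difference between trunk and head at BI on day 1 and AP on day 60. Without T0 libraries head minus trunk at BI on day 30 was 0.287 and pH in day 30 heads at B2 -0.119. Without variant and end CpGs 1-year F minus Y at AI was -1.15 in gonads and -0.472 in brains, pH at AI -0.761 in day 1 trunks and 0.12 in J brains, and Y minus R brains at AP 0.00586. Within pH treatments F minus Y brains at BI had -0.187, J minus F gonads -0.736 at AP and -0.976 at BI, and J minus Y gonads -1.48 at AP. Within sets F minus Y had -4.59 at BI in gonads and 0.935 at AP in brains, and J minus Y -1.21 at AP in gonads and 3.53 at B2 and 9.77 at BI in brains. For pH at day 30, sets RD6 3 and RD7 alone gave -3.41 at AP in heads and 5.54 at B2 in trunks, and T0 libraries alone -2.83 and 1.66. Set means for pH at 1 year gave 0.634 at AI in Y gonads, and 0 CpGs in female brains, where no exact permutation p under 0.1 is possible.

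With single fish left out, adult F minus male brains ranged over -0.683 to 2.12 at AI, -1.71 to 2.84 at AP, -0.624 to 5.03 at B2 and -18.1 to 3.04 at BI. For pH, day 1 heads had -0.882 to 0.249 at AP, -4.31 to 2.47 at B2 and -10.8 to 7.00 at BI, day 60 heads -2.13 to 0.0348 at AI, female brains -3.25 to 6.85 at B2, Y gonads -0.844 to 0.876 at AI, Y brains -0.442 to 1.72 at AP and -3.07 to 10.7 at B2, J gonads -0.656 to 1.90 at AI and -9.51 to 0.278 at B2, and J brains -7.33 to 4.14 at AI, -10.03 to 6.75 at AP and -15.5 to 2.65 at B2. The pH difference between trunk and head had -7.72 to 3.99 at BI on day 1 and -0.188 to 2.01 at AP on day 60. Adult gonads had -5.25 to 1.49 at AI and -2.52 to 3.31 at B2 for Y minus R, -4.97 to 1.06 at AP, -2.61 to 11.4 at B2 and -11.9 to 0.701 at BI for Y minus B, and -0.963 to 5.07 at AP, -3.51 to 10.5 at B2 and -1.72 to 10.9 at BI for R minus B. Brains had -1.20 to 0.451 at AP and -4.04 to 12.5 at BI for Y minus R and -2.87 to 3.10 at B2 for Y minus B. For 1 year minus adult, female brains had -0.00601 to 4.54 at AP and -2.36 to 18.8 at BI, Y gonads -2.54 to 0.986 at AP and Y brains -2.32 to 2.84 at B2.

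Over all alternatives on the percent scale, the adult gonad sex difference was -54.2 to -48.8 at AI, -21.1 to -16.9 at AP, -31.2 to -14.5 at B2 and -36.5 to -17.0 at BI, with an adjusted exact permutation p of 0.00195 to 0.0571 (0.00879 to 0.0571 at B2). Across ages that difference in gonads had an adjusted permutation p of 0.00016 to 0.00133, 0.000853 to 0.00372, 0.0122 to 0.101 and 0.0194 to 0.191 at AI, AP, B2 and BI. The other ranges of adjusted permutation p were 0.00391 to 0.0659 for the sex difference at B2 between tissues, 0.0448 to 0.435 and 0.0323 to 0.136 for female and Y brains at AI across ages, and 0.0440 to 0.313 for adult female brain minus gonad at AI. For 1-year brain minus gonad they were 0.00651 to 0.0112 and 0.0223 to 0.0313 at AP in females and Y males, and 0.0314 to 0.146, 0.0466 to 0.156 and 0.00167 to 0.0521 at BI in females, Y males and J fish. For J minus F and J minus Y brains at AI they were 0.0100 to 0.311 and 0.0135 to 0.2, and 0.0346 to 0.911 for J minus F gonads. Age gave 0.00554 to 0.0914 and 0.0438 to 0.723 in acidic heads and trunks and 0.00776 to 0.0914 and 0.00416 to 0.0914 in neutral heads and trunks at AI, and 0.00277 to 0.0914 and 0.00739 to 0.0914 at AP and B2 in neutral heads. Sets gave 0.00231 to 0.127 (AI, neutral heads), 0.0292 to 0.237 (AP, neutral trunks), 0.0133 to 0.0927 (B2, acidic heads) and 0.0364 to 0.159 (AI, acidic trunks).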

Other observations

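The test of AI read kinds and the counts of regrouped fish were chosen after the results were seen, and the CpGs named next were chosen after their values were seen and carry no test. Along AP, CpGs of adult female brains had a high and a lower part, with 98.9% ± 0.709 at -246A, 97.3% ± 1.60 at -232A and 97.1% ± 0.815 at -203A (n = 4), against 45.7% ± 21.4 at -96A, 66.4% ± 13.6 at -74A and 65.8% ± 13.8 at -65A. Gonads of the same females had 84.1% ± 8.94, 72.7% ± 8.68 and 71.3% ± 9.08 at the first 3 and 56.6% ± 11.3, 64.1% ± 12.6 and 68.0% ± 6.98 at the last 3. Gonads of adult Y males (n = 4) had 96.5% ± 1.80, 86.9% ± 3.76 and 92.4% ± 3.39, and 81.2% ± 19.9, 85.8% ± 7.09 and 87.1% ± 9.12. Along AI, -1339A had the highest mean in all 3 of these groups, with 37.3% ± 8.21 in gonads of females, 52.6% ± 4.69 in their brains and 80.5% ± 5.47 in gonads of Y males. The lowest means were 10.2% ± 6.00 at -1291A in gonads of females, 19.6% ± 4.17 at -1285A in their brains and 59.0% ± 16.8 at -1220A in gonads of Y males. The guanines of -1339A and -1220A vary between fish of the series.

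At -274A of AP, which lies 17 bases from the amplicon start, the deposited percent was 44.6% ± 1.17 over all fish libraries, with single libraries between 40.0% and 49.2%. The no-template controls had 37.4% and 29.5% there. Reads may carry primer bases so near an end, and whether the value at -274A measures fish DNA was not tested. It is part of every AP mean except without variant and end CpGs.

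AI reads in gonads of adult females were compared with the reads that independent CpGs would give. An excess of reads without methylation cannot tell 2 kinds of reads, with and without methylation, from CpGs that depend on each other. If the 10 CpGs of a read were independent, 10.7% of the reads would have no methylated CpG, while 47.2% ± 7.48 had none (n = 4), a mean ratio of 6.19 over the 4 fish, with 2.60 the lowest and 10.7 the highest. Gonads of adult males had 6.66% ± 3.56 such reads against 0.00184% under independence, and 1-year gonads 8.87% ± 3.67 against 0.0646%. Their mean ratios were 413068 and 9028, so the excess was not particular to adult females. Which cells the reads came from was not tested, and copies of the same molecule cannot be told from separate molecules.

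Counts of called CpGs were set against regroupings of the same fish, drawn at random where there are more than 100 and with the real grouping included. Only comparisons with called CpGs were regrouped. The CpG tests already permuted the same fish, so the shares below are no separate support for the calls. For brain against gonad, 1 of 100 sign changes gave as many CpGs in 1-year females (17, next highest 14), 1 of 64 in Y males (16 and 0), 1 of 100 in J fish (19 and 17) and 1 of 100 in adult males (20 and 3). For head against trunk, 1 of 64 did at day 1 (10 and 0), 1 of 100 at day 30 (12 and 7) and 2 of 100 at day 60 (12, with 13 in another). The share was under 0.05 for these, and for adult gonads of females and males (21 CpGs, 1 of 100, next highest 11) and 1-year against adult female gonads (18, 1 of 100, 13). The same holds for age in acidic heads (9, 1 of 100, 5), neutral heads (14, 1 of 100, 9) and neutral trunks (10, 1 of 100, 2), and for sets in neutral heads (10, 1 of 100, 1) and neutral trunks (6, 2 of 100, 6 in another). Chance could not be excluded for J against Y brains, with 1 CpG, 6 of 100 and up to 7 in others, nor for sets in acidic trunks, with 1 CpG, 7 of 100 and up to 3 in others. For J against F brains (10 CpGs, 1 of 100, next highest 7) and pH in female brains (5, 1 of 100, next highest 0) the share was also under 0.05, but regrouping ignored the sets, in which J fish and pH are unevenly spread. Within sets J against F gave 0 CpGs by permutation, and the AI difference of 4.83 points had an adjusted exact permutation p of 0.311. For pH in female brains the count was 0 at coverage minimums of 100 and 500 reads and without any of the 10 fish, AI had an adjusted exact permutation p of 0.190, and nothing was adjusted over the 12 pH comparisons of CpGs.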
